A study of Mus musculus with 6 samples.

How the data were processed

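RNA was sequenced from 6 mouse brain libraries of the RiboTag design, in which Cre recombinase switches on an HA-tagged copy of the ribosomal protein Rpl22 so that ribosomes of the recombined cells can be pulled down with an HA antibody. Per the labels' protocols, tamoxifen (100 mg/kg/day for 5 days) was given at 8 weeks of age and brains were taken 1 month later after perfusion with cold buffer, 3 mice were pooled for each sample, a part of the cleared homogenate was kept as input, and the rest was immunoprecipitated (IP) with HA antibody on protein A/G beads. Per the labels' protocols, a stranded total RNA library kit for low input (Takara SMARTer Pico, v3) was used. The groups were control input (1 library), control IP (2), icKO input (1) and icKO IP (2), where icKO stands for the inducible conditional knockout of Ank3. Groups and replicate numbers came from the sample titles. The title of icKO IP replicate 1 reads cKO and was taken as icKO.

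The authors' file holds raw read counts per gene symbol, deposited without normalization. Reads were trimmed with Trimmomatic 0.39 and aligned with STAR 2.7.10b to genome build mm10, per the submitters' processing notes. The read counter, its gene annotation, its strand setting and any handling of PCR duplicates or molecular identifiers are not given in the sources used here, so genes that overlap on opposite strands and close paralogs are uncertain. Of 24421 genes in the file, 10 had no value in either input library and were left out, which left 24411, of which 4697 had no count in any library. Of the symbols, 23350 (95.6%) were found in a mouse gene name table, 27 had been turned into dates by spreadsheet software, and 4 entries shared a symbol with another. Mitochondrially encoded mRNA had 0 measured members and is not analysed here.

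Library totals ran from 18968806 to 23930812 counts, and 3 counts corresponded to 0.125 to 0.158 CPM of the library totals. Gene levels are given as CPM with TMM factors applied, from all 6 libraries for single libraries and from the 4 IP libraries for IP means, so that the first do not average exactly to the second. Intervals given for shares and for ratios of input counts cover counting error only. Counts were scaled with TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (two-sided, genes kept by filterByExpr, Benjamini-Hochberg adjusted p under 0.05). The installed default of that version estimates the dispersion with the design first. The icKO and control IP libraries were compared in a fit of the 4 IP libraries alone, with a common biological coefficient of variation of 3.01%, 2 residual degrees of freedom and 29.7 prior degrees of freedom. IP was compared with input over all 6 libraries with genotype as a term. The difference between the genotype change in IP and that in input was tested over 4 groups, with each lone input assumed to vary like the IP pairs. The 2 inputs had no test: log2 ratios of CPM with a prior count of 2 were used, and list medians were placed among 10000 random lists matched on mean expression. The labels call the IP libraries biological replicates but do not say whether their pools held different mice, so the p-values measure only the spread between these samples, which may be technical. The replicate numbers carried no stated pairing, and no block was used.

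For lists of genes, limma 3.58.1 camera was run with a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over 27 lists. The 29 lists held 753 symbols, of which 716 were in the file by exact symbol, and 2 lists had fewer than 5 measured members and were not tested. They covered oligodendroglial stages, the axoglial junction, ankyrin-linked and other cytoskeleton, lipid synthesis, channels, the other cell types of brain, stress, ribosomes, mitochondria and signs of RNA or tissue handling. Symbols in more than 1 list numbered 50, so the lists are not independent. They included 24 of 38 paranode symbols and 21 of 40 mature oligodendrocyte symbols. The ankyrin and spectrin list shared 6 symbols with the paranode list. With a correlation estimated from these 4 or 6 libraries, no list passed in either comparison, and the adjusted p of each list under that setting is given beside its call. That setting also rests on the few residual degrees of freedom of the fit, 2 in the IP comparison. Its lost calls therefore do not show that correlation between genes undoes a list. Between genotypes the oxidative phosphorylation list had an estimated correlation of -0.0056, below the preset, and did not pass either. Lists, tests, the alternatives below and the rule for naming genes were fixed before the data were examined, except where a choice is said to be later. Always named were Ank3, Rpl22, Ank1, Ank2, 3 spectrins, protein 4.1 and paranodal genes, myelin genes and a marker or more of each main cell type. For both tested comparisons the 10 largest rises and falls among genes past the threshold with a mean of at least 5 CPM were named (for genotype, only where both icKO IP libraries lay on the same side of both control IP libraries), for the inputs the 5 largest ratios each way, for the interaction the 5 smallest p each way, and for each list past its test the 4 members with the smallest p and members that passed the gene test. Predicted genes, clones and small or ribosomal RNA genes counted in totals but were not named by rank. Some genes that this rule names are not reported here, but stayed in fits, lists and counts of genes tested.

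The procedure was tested on simulated data drawn from the real means and library sizes with 200 changed genes. Every gene was given the common dispersion of the IP pairs, so the recovered shares hold only for that spread. In the IP comparison of genotypes, 60.5% of 1.2-fold, 98.5% of 1.5-fold and 100% of 2-fold changes were recovered on 15017, 15015 and 15001 genes. For IP against input these shares were 74%, 99.5% and 100% on 15270, 15274 and 15262 genes, and for the interaction 3.5%, 77.5% and 98% on 15543, 15550 and 15553 genes. Of the calls, 8.02%, 3.46% and 2.98% were false between genotypes at these sizes. The false shares were 4.84%, 4.58% and 4.96% for IP against input and 0%, 5.43% and 3.62% for the interaction. A gene list was shifted as well, and between genotypes at 1.2-fold camera also called 1 other list. Alternatives tried were DESeq2 1.42.0 size factors and its Wald test, library totals, other filters on low counts, all libraries in one fit, the replicate block, genes higher in IP than input alone, each library left out, other size limits and prior counts for the inputs, and other list tests. Chosen after seeing the data were another edgeR setting, an offset for transcript length (known for 96.2% of tested genes), scaling to markers of other cell types (the neuron, astrocyte and microglia lists) or to mature oligodendrocyte genes, a test against a 1.5-fold change, and older symbols. Coordinates and transcript lengths came from GENCODE M21 (GRCm38, the mm10 build). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.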

Results

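RNA pulled down with HA-tagged ribosomes was profiled in mouse brains. Control mice carried the tamoxifen-inducible NG2-CreERTM driver and HA-tagged Rpl22. The icKO mice also carried floxed alleles of Ank3, the gene of the membrane scaffold ankyrin-G. Each library came from a pool of 3 brains. The 4 IP libraries were 2 control and 2 icKO samples. The 2 inputs, whole homogenate RNA taken before the pull-down, were 1 control and 1 icKO sample, so that differences between inputs have no replicate check. Total counts were 21129973 in the control input, 20754765 and 23930812 in the control IPs, 19919520 in the icKO input, and 19569611 and 18968806 in the icKO IPs. Counts of the control IP pair differed by 2.19 times sampling noise (chi-square per degree of freedom) and those of the icKO IP pair by 2.13 times. The factor was 5.63 between the inputs and 73.1 between a control and an icKO IP. The 45S ribosomal RNA gene took 3.84% and 3.34% of counts in the control and icKO inputs, 2.58% and 2.59% in the control IPs and 2.23% and 2.16% in the icKO IPs (95% Wilson intervals within 0.0082 points).

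Ank3 (ENSMUSG00000069601.14, chromosome 10, 69398773 to 70027438, plus strand, mm10) was read at 382 CPM (TMM-scaled over all 6 libraries) in the control input, 1386 and 1357 CPM in the control IPs, 347 CPM in the icKO input, and 1163 and 1166 CPM in the icKO IPs. In the fit of the 4 IP libraries, which has TMM factors of its own, it fell from 1348 ± 20.3 to 1145 ± 0.894 CPM (SD, n = 2 each), a log2 change of -0.23 ± 0.02 (SE) with adjusted p = 1.31e-10 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. That is 0.85 of the control level. When libraries were scaled to the mature oligodendrocyte list the log2 change was 0.44, a rise. The input ratio was -0.15 (log2). The count covers the whole gene and the labels do not give the deleted exons, so reads from outside the deleted part count as well, and the level checks the genotype labels only weakly. Rpl22, the tagged ribosomal protein gene, was at 50.2 ± 3.94 CPM in control and 43.0 ± 2.71 CPM in icKO IPs (SD, n = 2), a log2 change of -0.22 that was 0.45 when scaled to the mature oligodendrocyte list. Its adjusted p was 0.0078 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 0.0999 with the transcript length offset, where the log2 change was -0.14. Without control IP replicate 2 the log2 change of Rpl22 was -0.14, and without icKO IP replicate 2 it was -0.16.

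**Figure D1:**
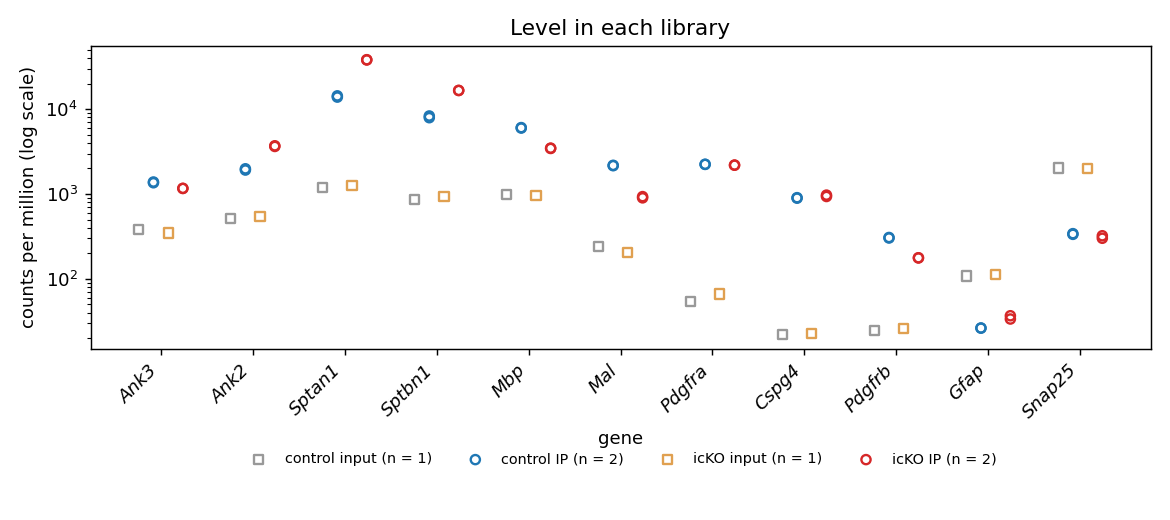
CPM (TMM-scaled over all libraries, log axis) of 11 genes in each of the 6 libraries, with 1 point per library, squares for inputs and circles for IPs. Ank3 lies at 382 and 347 in the inputs and between 1163 and 1386 in the IPs.

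The IP was first compared with the input to see which cells its RNA came from. Genes of oligodendrocyte precursors were far above input in the IP. Cspg4, which encodes NG2 and is also made by pericytes, was 41.4-fold above input (log2 5.37 ± 0.09 SE). Pdgfra, the growth factor receptor of precursors, was 37.0-fold above it (5.21 ± 0.12). Their adjusted p was 1.82e-09 and 3.12e-09 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 4 IP and 2 input libraries. All 26 measured genes of the precursor list rose in the IP, with a median log2 of 3.26. Myelin genes rose too, among them Mag (3.35), Cnp (3.22) and Mbp (2.22). Of 39 mature oligodendrocyte genes 36 rose and 2 fell (median 2.13). The other genes with the largest rises were Sapcd2 (5.39), Gpr17 (5.11), a receptor of committed precursors, Matn1 (5.05), Sox3 (4.90), Matn4 (4.82), Gsx1 (4.69), Neu4 (4.60) and Pnlip (4.58). Several of these ratios rest on few input counts. In the control and icKO inputs Matn1 was at 0.32 and 0.29 CPM, Gsx1 at 0.36 and 0.34, Pnlip at 0.50 and 0.34, Sapcd2 at 0.55 and 0.54, and Sox3 at 0.77 and 0.73. Pericyte and vascular smooth muscle genes were high too: 19 of 20 rose, 0 fell and the median was 3.38, with Abcc9 at 4.29 and Pdgfrb at 3.19.

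Other groups higher in the IP were the cell cycle list (25 of 25 rose, median 2.09, with Top2a at 3.11) and the paranode and axoglial adhesion list (26 rose and 5 fell of 36, median 1.84). They also included the ankyrin, spectrin and adducin list, tested without its protein 4.1 genes (11 rose and 4 fell of 17, median 0.68), and the sphingolipid and long-chain fatty acid list (16 rose and 5 fell of 30, median 0.72). Of the spectrins, the rods of the submembrane skeleton, Sptan1 (chromosome 2, 29965560 to 30031451) was 18.4-fold above input over both genotypes, with a log2 of 3.58 in control and 4.94 in icKO. Sptbn1 (chromosome 11, 30099395 to 30268175) was 12.8-fold above it (3.23 and 4.16), and the log2 for Sptbn4 was 1.49 over both genotypes. Of 10 nuclear-retained RNAs 8 rose and 1 fell (median 0.98), and all 6 sex-linked genes rose (median 1.35). Counts adjusted over the list alone were equal for these lists and for the precursor, mature oligodendrocyte and pericyte lists.

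Neuron genes fell in the IP, 29 of 30 (1 rose, median -1.94), with Snap25, a synaptic vesicle fusion gene, down 6.24-fold and Nrgn down 7.81-fold. Astrocyte genes (20 fell and 1 rose of 25, median -1.55, Gja1 -3.04) and microglia genes (22 fell and 0 rose of 24, median -2.25, Cx3cr1 -2.69) were lower as well. So were endothelial genes (15 fell and 1 rose of 20, median -1.38, Cldn5 -2.43) and choroid plexus genes (14 fell and 4 rose of 19, median -1.68). The genes with the largest falls were Ttr (-3.92), the transthyretin gene of the choroid plexus, Cartpt (-3.66), Pvalb (-3.34), Vip (-3.34), C1qc (-3.27), Hopx (-3.21), Penk (-3.19), Ctss (-3.19), Agt (-3.17) and Npy (-3.13). Axonal channel and node genes (19 fell and 4 rose of 26, median -0.68), immediate early genes (19 fell and 2 rose of 25, median -0.96) and clock genes (11 fell and 2 rose of 19, median -0.52) were lower too. Ribosomal protein genes (76 fell and 0 rose of 78, median -1.15) and oxidative phosphorylation genes (71 fell and 0 rose of 72, median -1.22) fell almost throughout. Adjusted over the list alone, 2 endothelial and 1 ribosomal protein gene rose and 12 clock genes fell, and the other counts were equal.

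In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 10811 of 15451 genes differed between IP and input (5382 higher and 5429 lower), 4779 of them by over 2-fold (2487 and 2292). Camera with Benjamini-Hochberg adjustment called 19 of 27 lists, and 0 with an estimated correlation (6 at an unadjusted p under 0.05), while limma's fry called 24. Among lists higher in the IP the camera adjusted p was 1.32e-42 for precursors (adjusted p = 0.195 with an estimated correlation), 7.79e-21 for pericytes (0.252) and 3.62e-18 for mature oligodendrocytes (0.252). It was 4.34e-12 for the paranode (0.195), 3.58e-08 for the cell cycle (0.142) and 9.94e-04 for sphingolipids (0.582). For sex-linked genes it was 0.0013 (0.293), followed by 0.0115 for ankyrins and spectrins (0.252) and 0.0379 for nuclear-retained RNA (0.617). Among lists lower in the IP it was 1.14e-33 for neurons (adjusted p = 0.1 with an estimated correlation), 6.46e-23 for ribosomal proteins (0.195) and 9.51e-18 for oxidative phosphorylation (0.293). Astrocytes followed with 9.43e-15 (0.0828), then 1.61e-08 for microglia (0.252), 3.62e-05 for axonal channels (0.252) and 7.66e-05 for immediate early genes (0.303). The largest were 0.0056 for endothelium (0.252), 0.0084 for choroid plexus (0.252) and 0.0496 for the clock (0.252). Without the control input the endothelial, choroid plexus and clock lists lost their call (adjusted p = 0.171, 0.113 and 0.105), as they did without the icKO input (0.0703, 0.196 and 0.0501). The clock list also lost it without any one IP library (0.056 to 0.0648). Actin and microtubule regulators gained a call without the icKO input (adjusted p = 1.26e-06).

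Lists that did not pass against input included actin and microtubule regulators (11 higher and 8 lower of 25, median 0.18, camera adjusted p = 0.139) and cholesterol synthesis (11 and 2 of 24, or 10 and 2 adjusted over the list alone, 0.20, adjusted p = 0.139). Interferon and antigen presentation (10 and 3 of 25, or 9 and 2 adjusted over the list alone, 0.35, adjusted p = 0.173) and disease-associated oligodendrocyte genes (14 and 9 of 24, 0.58, adjusted p = 0.358) did not pass either. The same held for heat shock (6 and 13 of 27, -0.13, adjusted p = 0.398), oligodendrocyte ion channels (16 and 14 of 34, or 18 and 14 adjusted over the list alone, adjusted p = 0.588), fibroblasts (3 and 8 of 15, -0.26, adjusted p = 0.736) and the integrated stress response (7 and 10 of 22, -0.24, adjusted p = 0.743). For ion channels the median was 0.22 and the mean 0.04, while the camera direction was down. Without the icKO input the camera direction turned to up for fibroblasts (adjusted p = 0.976) and the integrated stress response (0.757). The 3 measured erythrocyte genes all fell (median -2.11) and were too few for a list test.

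Between genotypes, the design asks how loss of ankyrin-G alters the transcripts that oligodendroglial ribosomes carry. Spectrins and the related ankyrin Ank2 rose in the icKO IP. Sptan1, the alpha chain partner of the beta spectrins, went from 13887 ± 340 to 37600 ± 236 CPM (SD, n = 2 each, log2 1.44 ± 0.02 SE, adjusted p = 2.66e-35) and Sptbn1 from 7993 ± 267 to 16372 ± 3.78 CPM (1.03 ± 0.02, adjusted p = 3.98e-30). Sptbn4 (0.99), Sptb (0.67) and Ank2 (0.91, chromosome 3, 126921612 to 127499350) rose with them, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. These 4 spectrin genes together took 2.59% and 2.52% of all counts in the control IPs and 5.71% and 5.70% in the icKO IPs, against 0.265% and 0.281% in the control and icKO inputs (95% Wilson intervals within 0.0104 points). Of the 17 measured genes of the ankyrin, spectrin and adducin list 9 rose and 5 fell, the same counts when adjusted over the list alone, and the median was 0.21 but 0.07 with the transcript length offset and -0.0043 when scaled to markers of other cell types. Its camera adjusted p was 7.22e-22 (adjusted p = 0.12 with an estimated correlation). The protein 4.1 genes of this list have older symbols in the file and were not among the 17. With older symbols 24 genes were tested and the camera adjusted p was 1.96e-15. Besides Ank3, the falling members were the adducins Add1 and Add3 and the tropomodulins Tmod1 and Tmod2 (-0.18 to -0.22). Ank1 was at 0.21 (adjusted p = 1.84e-04) but -0.0043 when scaled to markers of other cell types, and its adjusted p was 0.211 with the transcript length offset.

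Myelin genes fell in the icKO IP. Mbp, the cytoplasmic myelin basic protein gene (chromosome 18, 82475146 to 82585637), went from 5927 ± 55.5 to 3404 ± 25.2 CPM (SD, n = 2 each, log2 -0.80 ± 0.02 SE, adjusted p = 5.52e-27). Mal (-1.24), Mobp (-1.09), Mog (-0.76), Cldn11 (-0.74), Cnp (-0.40) and Mag (-0.28) fell as well in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Scaled to the mature oligodendrocyte list, which adds 0.68 to every value, Mag and Cnp were at 0.39 and 0.27. Of 39 mature oligodendrocyte genes 34 fell and 2 rose, also when adjusted over the list alone (median -0.68, camera adjusted p = 4.14e-61, adjusted p = 0.12 with an estimated correlation). The rising members were Hapln2, a link protein of the nodal matrix (0.50), and Gsn, the actin-severing gelsolin (0.08). Of 26 precursor genes 22 fell and 1, Cspg4 (0.08), rose, also when adjusted over the list alone, with a median of -0.26 that was 0.42 when scaled to the mature oligodendrocyte list. The list's adjusted p in camera was 1.22e-10 (adjusted p = 0.135 with an estimated correlation). Lhfpl3 (-0.66) and the lineage transcription factors Olig2 (-0.57), Olig1 (-0.55) and Sox10 (-0.42) fell. Pdgfra was at -0.03 (adjusted p = 0.226), a value that rested on the setting. It passed at -0.05 without a filter (adjusted p = 0.0358), -0.12 with library totals (9.55e-06), -0.13 with the length offset (1.95e-06) and -0.24 when scaled to markers of other cell types (3.51e-11). It was at 0.65 when scaled to the mature oligodendrocyte list (7.72e-28) and 8.68e-04 among genes of at least 5 CPM (0.975). For Cspg4 the adjusted p was 0.0041 in the same test, and its log2 change of 0.085 was 0.056 without icKO IP replicate 2. Its sign turned with library totals (-0.0013), with the length offset (-0.05) and when scaled to markers of other cell types (-0.13).

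**Figure D2:**
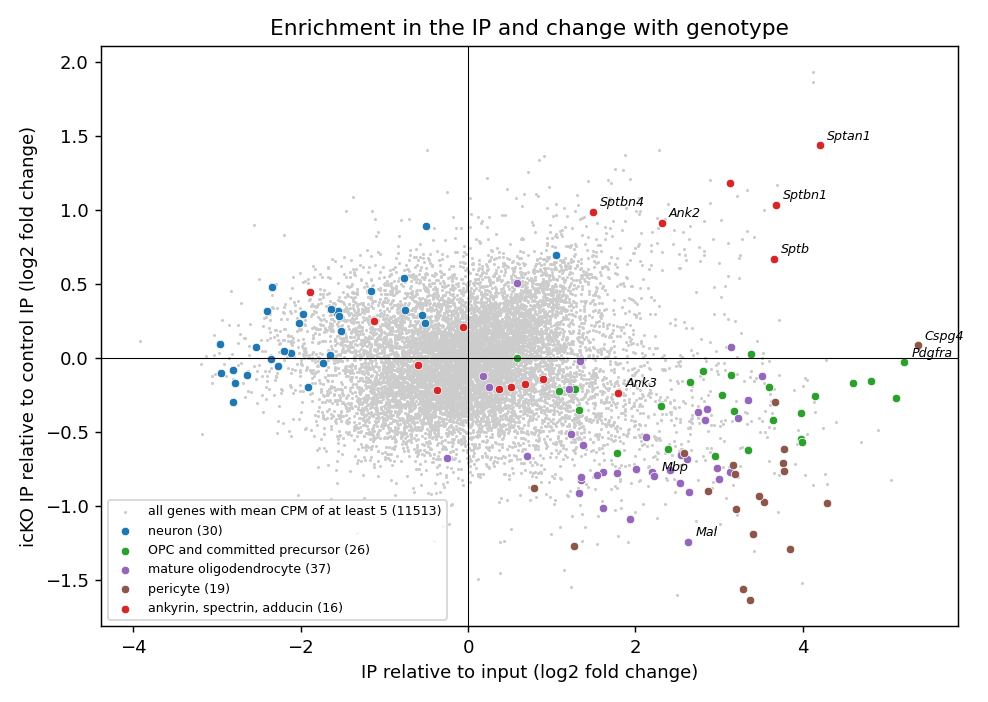
Log2 fold change of icKO IP relative to control IP (vertical axis) against that of IP relative to input (horizontal axis) for 11513 genes with a mean of at least 5 CPM, with colours for gene lists. Sptan1 lies at 4.2 (horizontal) and 1.44 (vertical), Mbp at 2.22 and -0.80, where scaling to the mature oligodendrocyte list adds 0.68 to every vertical value and scaling to markers of other cell types shifts them by -0.215.

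At the axoglial junction, 22 of 36 genes fell and 9 rose, also when adjusted over the list alone, with a median of -0.27 that was 0.41 when scaled to the mature oligodendrocyte list. Camera gave the list an adjusted p of 8.89e-04 (adjusted p = 0.148 with an estimated correlation). Tspan2 (-0.82) and Cntn1, the contactin of the axonal side of the paranode (-0.17), were among those that fell. Those that rose included Sptan1, Sptbn1 and Ank2, already given with the ankyrin and spectrin list, and Cntnap1, the contactin-associated protein Caspr (0.29). Cntnap1 was at 0.08 with an adjusted p of 0.227 when scaled to markers of other cell types. Nfasc, which encodes the paranodal neurofascin, was at -0.05 with an adjusted p of 0.0309 that rose to 0.0866 without icKO IP replicate 1 and 0.439 among genes of at least 5 CPM. The protein 4.1 genes, not counted in the list under their older symbols, were given singly: Epb4.1l3 (-0.24, adjusted p = 1.80e-07) and Epb4.1l2 (-0.07, adjusted p = 0.0504) were at 0.44 and 0.61 when scaled to the mature oligodendrocyte list. Epb4.1l2 was at -0.15 with library totals (adjusted p = 4.13e-05) and -0.28 when scaled to markers of other cell types (4.05e-09). It also passed without a filter (0.0116), among genes higher in IP than input (0.0471) and with the replicate block (0.0495). The same held without control IP replicate 1 (0.0334) and without icKO IP replicate 2 (0.0402), in the same quasi-likelihood test.

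Among cytoskeletal regulators of oligodendrocytes, without the septins, whose symbols had turned into dates, 21 of 25 fell and 3 rose, also when adjusted over the list alone, with a median of -0.36 that was 0.32 when scaled to the mature oligodendrocyte list. Its camera adjusted p was 6.38e-22 (adjusted p = 0.12 with an estimated correlation). Those that fell included Tubb4a (-0.55), Actb (-0.50) and Ermn (-0.78), an oligodendrocyte cytoskeletal protein. Sphingolipid and long-chain fatty acid genes fell in 19 of 30 cases, or 21 when adjusted over the list alone, with 0 rising and a median of -0.29 that was 0.38 when scaled to the mature oligodendrocyte list. The list's adjusted p in camera was 2.63e-08 (adjusted p = 0.12 with an estimated correlation). Fa2h, the fatty acid 2-hydroxylase of myelin lipids (-0.85), and the desaturases Scd1 (-0.81), Degs1 (-0.67) and Scd2 (-0.57) led that list. Disease-associated oligodendrocyte genes fell in 18 of 24 cases and rose in 0, also when adjusted over the list alone, with a median of -0.39 that was 0.29 when scaled to the mature oligodendrocyte list (camera adjusted p = 6.92e-06, adjusted p = 0.12 with an estimated correlation), among them Il33 (-0.91), Cd63 (-0.84), Apoe (-0.53) and Cd9 (-0.41). Integrated stress response genes fell in 10 of 22 cases, or 12 when adjusted over the list alone, and 1 rose, with a median of -0.29 that was 0.38 when scaled to the mature oligodendrocyte list. DESeq2 called 6 of them lower. Their camera adjusted p was 0.0324, and adjusted p = 0.239 with an estimated correlation and 0.0768 with the transcript length offset ended that call. Ddit4 (-0.66), the serine synthesis genes Phgdh (-0.51) and Psat1 (-0.44), and Vldlr (-0.19) fell.

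Ribosomal protein genes fell in 71 of 78 cases and rose in 0, also when adjusted over the list alone, with a median of -0.32 that was 0.36 when scaled to the mature oligodendrocyte list (camera adjusted p = 4.14e-11, adjusted p = 0.183 with an estimated correlation), for example Rpl13 (-0.47) and Rpl8 (-0.42). With the transcript length offset 25 of them fell and the median was -0.11 (camera adjusted p = 0.0251). Nuclear-encoded oxidative phosphorylation genes fell in 65 of 72 cases, or 66 when adjusted over the list alone, and 1, Ndufs1, rose, with a median of -0.385 that was 0.29 when scaled to the mature oligodendrocyte list (camera adjusted p = 2.50e-09, adjusted p = 0.12 with an estimated correlation), with Uqcrq at -0.76 and Cox6c at -0.55. With the length offset 37 of these fell and the median was -0.19 (camera adjusted p = 0.003).

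Markers of other cells and signs of RNA handling moved with the genotype as well. Neuron genes rose in 17 of 30 cases and fell in 3, also when adjusted over the list alone, with a median of 0.21. Scaled to markers of other cell types it was -0.005, but that scaling uses this list itself, so a median near 0 is by construction. Camera gave the list an adjusted p of 3.72e-06 (adjusted p = 0.155 with an estimated correlation). The largest rises were the neurofilament Nefh (0.89), the non-coding Snhg11 (0.70), which is also in the nuclear-retained list, and the neurofilament Nefm (0.54). On the other side, Vsnl1 (-0.30), Tubb3 (-0.20) and Snap25 (-0.12) fell. Snap25 was at -0.07 without icKO IP replicate 2. With the length offset it was at -0.04 (adjusted p = 0.344 in edgeR's quasi-likelihood test). Axonal channel and node genes rose in 17 of 26 cases, or 20 when adjusted over the list alone, and 4 fell, with a median of 0.24 (camera adjusted p = 3.18e-04). That call was lost with an estimated correlation (adjusted p = 0.239) and with the transcript length offset (0.0768). Scaled to markers of other cell types the median was 0.03, with 6 rising and 7 falling. The falling members were Cntn2 (-0.42), Kcna1 (-0.39), Ckb (-0.26) and Nfasc. Pericyte genes fell in 19 of 20 cases and only Cspg4 rose, also when adjusted over the list alone (median -0.92, camera adjusted p = 4.21e-25, adjusted p = 0.12 with an estimated correlation), with Rgs5 at -1.19, Abcc9 at -0.98, Vtn at -0.93 and Pdgfrb at -0.79. Nuclear-retained RNAs rose in 9 of 10 cases and fell in 0, also when adjusted over the list alone (median 0.70, camera adjusted p = 4.80e-39, adjusted p = 0.12 with an estimated correlation), among them Xist (1.86), Malat1 (0.84), Kcnq1ot1 (0.77), Snhg11 (0.70) and Meg3 (0.65). Xist is also in the sex-linked list, so that part of this rise may reflect the sex of the pools. With the length offset 7 of the 10 rose and the median was 0.48.

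The sex-linked list split, with Xist and Tsix up and the Y-linked Ddx3y (-1.24), Kdm5d (-0.93), Eif2s3y (-0.89) and Uty (-0.78) down, so that its median was -0.83, its mean -0.0053 and its camera direction up. Its camera adjusted p was 0.0616, and 0.0017 and 0.0012 without icKO IP replicate 1 and 2. The direction turned to down without control IP replicate 1 (adjusted p = 0.94) and without control IP replicate 2 (0.672). Xist, the RNA that silences an X chromosome in females (chromosome X, 103460366 to 103483254), went from 669 ± 42.0 to 2431 ± 5.02 CPM (SD, n = 2 each, log2 1.86, adjusted p = 3.38e-32 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Tsix (1.93) overlaps Xist on the other strand (103431517 to 103484957), and without the strand setting of the counting their reads cannot be told apart.

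The largest rises in the icKO IP among genes of at least 5 CPM were, after Tsix and Xist, Sptan1 (1.44), the collagen gene Col1a1 (1.41), which also had an input ratio of 1.22, the actin-binding drebrin Dbn1 (1.40), Micalcl (1.37), Nexn (1.36), Miip (1.34), Neb (1.27) and the non-muscle myosin Myh10 (1.27). The largest falls were Ndufa4l2 (-1.64), Casq2 (-1.60), Higd1b (-1.56), Slc16a3 (-1.55), Tbxa2r (-1.52), Arhgdib (-1.49), Mgp (-1.45), Shisa8 (-1.43), Tbx2 (-1.31) and Kcnj8 (-1.29), of which Ndufa4l2, Higd1b and Kcnj8 were in the pericyte list. Each of these 20 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the largest adjusted p being 7.03e-08 for Slc16a3.

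In that test 7119 of 15069 genes differed between the icKO and control IPs, 3326 higher and 3793 lower, and 382 of them by over 2-fold, 272 higher and 110 lower. Among genes of at least 5 CPM only 91 passed with over 2-fold (52 higher and 39 lower, or 57.1% higher), so most of the 382 were genes under 5 CPM. Tested against a change of 1.5-fold 271 genes passed (136 higher and 135 lower). The balance of rises and falls rested on the scaling: 46.7% of calls were higher, but 32.6% with library totals (2409 higher and 4979 lower). The share was 16.7% when scaled to markers of other cell types (1368 and 6820) and 99.1% when scaled to the mature oligodendrocyte list (12657 and 120). Beyond 2-fold the share of higher calls was 71.2%, against 54.3%, 28.9% and 99.7% under those scalings (185 and 156, 116 and 285, and 3059 and 10 genes). Scaling to markers of other cell types moved the median of all genes by -0.215 and scaling to the mature oligodendrocyte list by 0.677, so that each change here is relative to the TMM scaling. Camera called 14 of 27 lists, 4 higher and 10 lower, and 0 with an estimated correlation (9 at an unadjusted p under 0.05), while limma's fry called 22.

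Lists without a call between genotypes were heat shock (3 higher and 15 lower of 27, median -0.17, camera adjusted p = 0.0907) and oligodendrocyte ion channels (12 and 17 of 34, or 13 and 18 adjusted over the list alone, -0.12, adjusted p = 0.0907). Others were cholesterol synthesis (1 and 11 of 24, -0.15, adjusted p = 0.0994), the cell cycle (12 and 1 of 25, 0.38, adjusted p = 0.113) and the clock (8 and 2 of 19, or 8 and 3 adjusted over the list alone, 0.04, adjusted p = 0.174). Nor did a call stand for interferon and antigen presentation (1 and 8 of 24, -0.22, adjusted p = 0.202) or endothelium (2 and 4 of 20, or 1 and 4 adjusted over the list alone, -0.28, adjusted p = 0.311). Glial lists without a call were microglia (3 and 2 of 23, 0.25, adjusted p = 0.322) and astrocytes (12 and 5 of 25, or 12 and 7 adjusted over the list alone, 0.18, adjusted p = 0.51). Of these, heat shock passed without control IP replicate 1 (adjusted p = 0.0294) and without icKO IP replicate 1 (0.0437). Cholesterol synthesis passed without control IP replicate 2 (0.0288) and ion channels with the transcript length offset (0.0014). Without control IP replicate 1 the microglia median was 0.43 and the astrocyte median 0.10. Without control IP replicate 2 the clock median was 0.11 and 9 heat shock genes fell, and without icKO IP replicate 1 the cell cycle median was 0.22. Signs differed between median and mean or test for immediate early genes (6 and 4 of 25, median -0.0027, camera up, adjusted p = 0.695) and choroid plexus (3 and 4 of 17, median 0.22, camera down, adjusted p = 0.916). For fibroblasts (4 and 3 of 14) the median was -0.13, the mean 0.0037 and the camera direction down (adjusted p = 0.988). Without control IP replicate 2 the fibroblast median was 0.07 and without icKO IP replicate 1 it was 0.03, both with camera up (adjusted p = 0.885 and 0.893), and without icKO IP replicate 2 it was -0.03. Camera was up for choroid plexus without control IP replicate 2 (adjusted p = 0.776), and its median ran from 0.13 without icKO IP replicate 1 to 0.37 without control IP replicate 1. For immediate early genes the median was above 0 without any one library (0.0113 to 0.16). Single markers were Gfap of astrocytes (0.42, adjusted p = 5.15e-05), Cx3cr1 of microglia (-0.17, adjusted p = 0.455) and Cldn5 of endothelium (-0.39, adjusted p = 0.301). Of the 3 measured erythrocyte genes 2 fell and 0 rose (median -0.95).

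**Figure D3:**
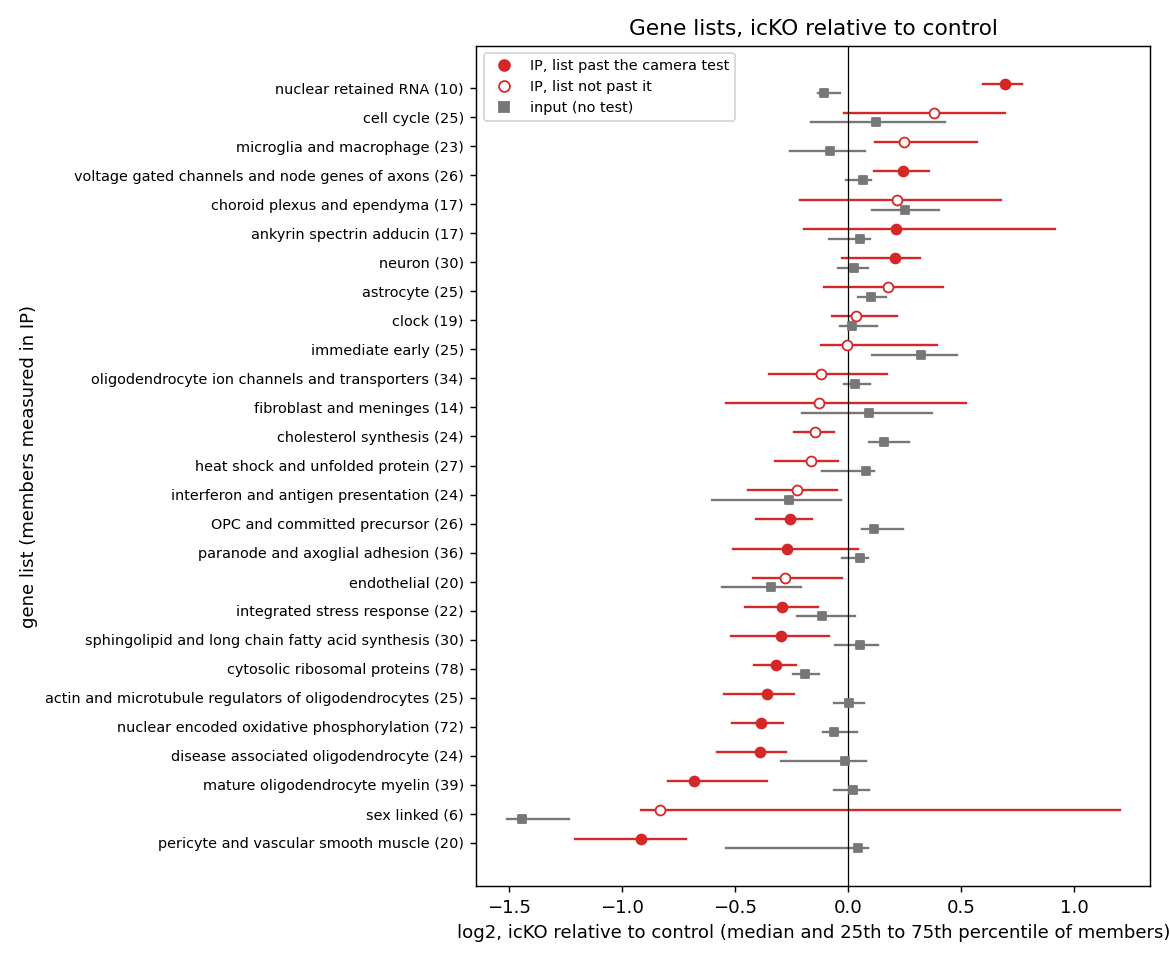
Median log2 of each gene list with at least 5 measured members, icKO relative to control, with bars from the 25th to the 75th percentile of members, in red for the IP (filled where the camera test passed) and in grey for the inputs, 1 library each. The mature oligodendrocyte list lies at -0.68 in the IP and 0.02 in the input, and scaling to that list moves all plotted IP medians but its own and those of the pericyte and sex-linked lists to above 0.

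The inputs were compared to see whether whole brain RNA differed. Among 11525 genes of at least 5 CPM, 20 differed by over 2-fold, 9 higher and 11 lower in the icKO input, which compares these libraries and not the genotypes. The highest ratios were Psapl1 (log2 1.61, exact 95% interval of the count ratio 1.18 to 2.12, 53 and 156 counts), Scd3 (1.38, 1.10 to 1.70) and Bpifa6 (1.33, 1.08 to 1.61). They were followed by Col1a1 (1.22, 1.02 to 1.44) and Cyr61 (1.2, 0.83 to 1.63). The lowest were Vwf, the endothelial von Willebrand factor gene (-1.75, -1.95 to -1.56, 1008 and 282 counts), the Y-linked Uty (-1.66, -2.02 to -1.35), Ddx3y (-1.51, -1.71 to -1.32) and Eif2s3y (-1.44, -1.83 to -1.10), and Alas2 of erythroid cells (-1.38, -1.66 to -1.12). Mature oligodendrocyte genes had a median ratio of 0.02, at percentile 73.8 of random lists, and the ankyrin and spectrin list 0.05 (90.8).

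Further input medians above 0 with their percentiles were 0.12 for precursors (99.95), 0.05 for the paranode (97.3), 0.005 for actin and microtubule regulators (27.5), and 0.16 for cholesterol synthesis (100). They were 0.05 for sphingolipids (95.2), 0.03 for ion channels (81.6), 0.07 for axonal channels (99.1), and 0.10 for astrocytes (100). Next came 0.03 for neurons (63.6), 0.04 for pericytes (75.4), 0.09 for fibroblasts (93.4), and 0.25 for choroid plexus (99.9). The rest were 0.32 for immediate early genes (100), 0.02 for the clock (61.8), 0.08 for heat shock (99.2) and 0.13 for the cell cycle (89.0). Below 0 were endothelium (-0.34, percentile 0), interferon and antigen presentation (-0.26, 0.13), ribosomal proteins (-0.19, 0), and the integrated stress response (-0.12, 0.965). So were nuclear-retained RNA (-0.11, 0.2), microglia (-0.08, 9.94), oxidative phosphorylation (-0.06, 0.01), disease-associated oligodendrocyte genes (-0.01, 39.6) and 5 sex-linked genes (-1.44, 0).

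The genotype change in the IP was then set against that in the input in one model. Sptan1 went from 3.58 to 4.94 above input (log2, interaction 1.35, adjusted p = 1.82e-25). The interaction was 1.24 for Ppp1r9a, the actin-binding neurabin, 1.25 for Myh10 and 1.37 for Dbn1. Mbp went from 2.63 to 1.86 above input (-0.77, adjusted p = 9.31e-18). Ptgds (-1.13), Mal (-1.02) and Aplp1 (-0.76) lay on the same side. Ank3 had an interaction of -0.10 (adjusted p = 0.0729), with an adjusted p of 0.0463 without control IP replicate 2, 0.0451 without a filter and 0.002 with library totals. Cspg4 was at 5.36 in control and 5.37 in icKO above input (adjusted p = 0.959), and Pdgfra at 5.37 and 5.05 (-0.33, adjusted p = 3.26e-05). The input of Pdgfra went from 53.9 to 66.1 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 3763 of 15936 genes passed, 1541 higher and 2222 lower in IP. That is 41.0% higher, against 28.0% with library totals (1153 and 2965). Beyond 2-fold 293 passed (169 and 124, 57.7% higher), against 43.7% with library totals (138 and 178). DESeq2 called 1709 and, beyond 2-fold, 52. The spread in this test comes from the IP pairs alone.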

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

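All tests of explanations in this part were chosen after the result was seen, while the test of the difference between IP and input was fixed before the data were examined.

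The change with genotype differed between IP and input for 3763 genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1541 higher and 2222 lower in the IP, with each lone input assumed to vary like the IP pairs. Of 49 named genes tested 34 passed, against 23.6% of all 15936 genes tested. The named genes include those picked for the smallest p in this same test or for the largest genotype change in the IP. Their share was therefore raised by the selection and is no separate result. Those on the higher side (log2 difference) were Dbn1 (1.37), Sptan1 (1.35), Micalcl (1.3), Myh10 (1.25), Ppp1r9a (1.24), Nexn (1.08), Sptbn1 (0.92), Sptbn4 (0.87) and Ank2 (0.84), with Xist at 0.71, Gfap at 0.34 and Cntnap1 at 0.22. Myelin and lineage genes on the lower side were Ptgds (-1.13), Olig2 (-1.07), Mal (-1.02), Mog (-0.79), Mbp (-0.77), Aplp1 (-0.76), Cldn11 (-0.66), Sox10 (-0.55), Cnp (-0.53), Mag (-0.34) and Pdgfra (-0.33), with the junction genes Epb4.1l3 (-0.41), Cntn1 (-0.27), Nfasc (-0.24) and Epb4.1l2 (-0.20) and the tag gene Rpl22 (-0.31). Ndufa4l2 (-1.74), Casq2 (-1.44), Arhgdib (-1.42), Mgp (-1.28), Shisa8 (-1.08) and Pdgfrb (-0.88) were lower too. Some of these values come partly or mostly from the lone inputs. Pdgfra was at 2241 and 2236 CPM in the control IPs and 2195 and 2185 CPM in the icKO IPs. Its input went from 53.9 to 66.1 CPM. Olig2 fell in the IP, but its input also went from 14.6 to 20.7 CPM. Nfasc was at -0.05 (log2) in the IP, and Epb4.1l2 at -0.07 with an input ratio of 0.11. Rpl22 lost its call without control IP replicate 2 (adjusted p = 0.191) and without icKO IP replicate 2 (0.0972), Cntnap1 without control IP replicate 2 (0.0556) and Gfap without icKO IP replicate 1 (0.0577). Calls were also lost in DESeq2 for Rpl22 (0.234), Epb4.1l2 (0.0703), Cntnap1 (0.183) and Gfap (0.164), with library totals for Cntnap1 (0.114) and among genes of at least 5 CPM for Rpl22 (0.0565).

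Sptan1, Sptbn1, Sptb and Sptbn4 took 2.52% to 2.59% of counts in the control IPs and 5.70% to 5.71% in the icKO IPs. Carry-over of whole-brain RNA into the icKO IP alone was argued against, since a mixture with it lies between control IP and input. The lower icKO IP share of each gene exceeded that in every control IP and input library by at least 0.53 (log2, replicates within 0.09). This order restates the rise for which the genes were picked. More carry-over in the control IP would give the same order and stays open. Transcript length alone was argued against too, since their median log2 change was 0.85 with a length offset and 4 of 4 genes still passed. Capture of cytoskeletal mRNA from cells without the tag stays open. Sptbn4, Ppp1r9a and Dbn1 had a median of 1.65 (log2) above input in the control IP (1.07 to 3.12), but this decides nothing, because these genes were picked from among those that changed with the genotype. A change within tagged cells caused by the genotype also stays open and cannot be told apart from it, because IP preparations follow the genotype: the input median was 0.10, and no library separates these explanations.

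Mature oligodendrocyte and pericyte genes were lower in the icKO IP. A common dilution of all tagged cells alone was argued against, since the oligodendrocyte list lay further down than the precursor list (difference of medians -0.42, permutation p = 3.10e-04 across genes, which are not independent replicates), and the pericyte list further still (-0.68, p = 1.00e-05, the smallest that 100000 resamples can give). Unequal falls do not exclude dilution as a shared part of the change, which stays open. IP medians were 0.21 for neurons, 0.18 for astrocytes and 0.25 for microglia, but -0.28 for endothelium and -0.13 for fibroblasts. Length bias was argued against by a median of -0.58 with the offset. Fewer mature oligodendrocytes in the brain stays open: the input median was 0.022 (25th to 75th percentile -0.06 to 0.09) beside -0.68 in the IP, but 1 input library per genotype excludes nothing. Less vessel tissue in the icKO pool may explain part of the pericyte change and stays open, since their input median was 0.0428 but ranged from -0.54 to 0.09 between quartiles, with the endothelial list at -0.34. Lower recombination or tagging in these cells, and a change caused by the genotype, were not separated by any library.

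Sex-linked genes differed between genotypes. A different sex make-up of the pools may account for this: the median of 4 Y-linked genes was -1.47 in the input and -0.91 in the IP, and Xist was at 1.13 and 1.86. A mislabelled IP library was argued against, since the Y-linked sum differed by at most 0.0745 (log2) between the IP libraries of a genotype and by at least 1.04 between genotypes. Whether both IP libraries of a genotype came from the same pool cannot be told (chi-square of the Y-linked sums, adjusted p = 0.324). As sex and genotype then go together, differences between sexes stay an open, untested explanation for any gene.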

How the results depend on the processing

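The tests with legacy = FALSE, the length offset, both scalings to marker lists, the 1.5-fold test and older symbols were chosen after the result was seen. Of the counts of genes and lists, 97 values under alternatives stayed within 1.5 times the value reported and 15 did not. For single named genes 3551 values kept their direction and call, 63 lost the call (39 of them in the 1.5-fold test), 22 gained one and 42 changed sign. The planned legacy = TRUE is the setting of the reported fit and moves nothing. DESeq2 gave no adjusted p for 16 named genes in the interaction, which are left out of these counts.

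Leaving out 1 library at a time gave 5905 to 6242 genes between genotypes (331 to 357 over 2-fold), 10106 to 11076 between IP and input (4657 to 4966), 3515 to 3889 in the interaction (324 to 350), 15 to 16 lists between genotypes and 16 to 18 between IP and input. Where this left an arm with 1 library, it was assumed to vary like the others. The replicate block gave 7277 genes, 409 over 2-fold and 14 lists, and among named genes it changed the call of Epb4.1l2 only. Libraries with the same replicate number showed no shared deviation (correlation of deviations -0.01 across genes), which does not exclude a pairing. A crossed pairing was not run.

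Beyond 2-fold between genotypes DESeq2 called 236 genes and the 5 CPM filter left 91. In the reported fit only 89 of 11513 genes of at least 5 CPM lay beyond 2-fold, so most calls of that size were genes under 5 CPM. Genes higher in IP than input gave 3980 calls because fewer were tested. Scaling to the mature oligodendrocyte list gave 12777 and 3069, and the 1.5-fold test 271 and 116, by construction. In the interaction DESeq2 gave 1709 and 52, and the 5 CPM filter 149 beyond 2-fold. The input comparison gave 136 genes at 1 CPM and 7 at 20 CPM, as more or fewer genes entered. Lists past the test numbered 0 between genotypes and 0 between IP and input with an estimated correlation (9 and 6 at an unadjusted p under 0.05). That setting also rests on the few residual degrees of freedom of the fit, so these losses are not due to correlation between genes alone. The fry test, which tests against no change, called 22 and 24. For DESeq2 the cause was not tested.

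Signs turned between genotypes for Cspg4 with library totals (-0.0013), the length offset (-0.0541) and scaling to other cell types (-0.13), for Ank1 with the last (-0.0043), and for Pdgfra with the 5 CPM filter (8.68e-04). In the interaction they turned with library totals for Ank1 (-0.0541) and Cspg4 (-0.0591), and for Cspg4 without control IP replicate 1 (-0.0027) and without icKO IP replicate 2 (-0.0159), with 0.0382 without icKO IP replicate 1 as the highest. Between genotypes library totals moved all genes by a median of -0.0863 and scaling to other cell types by -0.215. These shifts by construction turned the small values of Cspg4 and Ank1 under those settings. For the other sign changes given so far the cause was not tested. Scaling to the mature oligodendrocyte list adds 0.68 to every value, which by construction turned Ank3 (0.44), Rpl22 (0.45), Epb4.1l2 (0.61), Epb4.1l3 (0.44), Nfasc (0.63), Cntn1 (0.505), Mag (0.39), Cnp (0.27), Sox10 (0.26), Olig2 (0.11), Olig1 (0.13), Pdgfra (0.65), Lhfpl3 (0.0146), Snap25 (0.56), Cx3cr1 (0.51), Cldn5 (0.28), Tubb4a (0.13), Actb (0.17), Scd2 (0.11), Degs1 (0.0051), Cntn2 (0.26), Kcna1 (0.29), Psat1 (0.24), Phgdh (0.17), Ddit4 (0.0192), Vldlr (0.48), Apoe (0.15), Cd9 (0.27), Rpl13 (0.21), Rpl8 (0.25), Rpsa (0.29), Cox6c (0.13) and Atp5b (0.39).

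Depth was not varied. In data simulated at the depth of these libraries the interaction, which rests on 1 input per genotype, recovered 3.5% of 1.2-fold changes, against 60.5% between genotypes in the IP.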

Other observations

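The families in this part were chosen after the result was seen, and only the test of the myosin correlation was written down before its result.

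Some actin-linked families beyond the spectrins were high in the icKO IP. All 3 measured alpha-actinins, which crosslink actin filaments, rose (Actn2 1.2 on the log2 scale, Actn1 1.19, Actn4 1.01), as did 3 of 4 plakins, giant linkers between filament systems (Macf1 0.93, Plec 0.93, Dst 0.85, with Evpl at 0.20 and an adjusted p of 0.317). Of 22 myosin heavy chains 16 rose and 3 fell (median 0.38), led by Myh10 (1.27), Myo5a (1.08), Myo18b (1.03) and Myh9 (0.89). Their input ratios (log2) were -0.0044, 0.03, 0.57 and 0.08, so that the input of Myo18b moved the same way as its IP. Myh11 of smooth muscle fell (-0.72, input ratio -0.63). These medians stayed above 0 under every scaling tried, with the lowest at 0.98 for alpha-actinins, 0.51 for plakins (length offset) and 0.17 for myosins. Counts are of single genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and as the families were picked from genes seen to change, no test of a family as a whole is given.

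Tropomyosins went the other way, with 0 rising and 3 falling of 4 and a median of -0.42 that was 0.26 when scaled to the mature oligodendrocyte list. Kinesins had a median of 0.13 that was -0.09 when scaled to markers of other cell types (10 rose and 3 fell of 25, with 4 rising under that scaling), and filamins and talins one of 0.16 that was -0.06 under that scaling (2 rose and 1 fell of 4). Among the septins, whose symbols had turned into dates, Sept4, a septin of myelin, was at -0.73 (adjusted p = 1.86e-21) and Sept7 at -0.40 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

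A hypothesis was that the icKO IP holds more of whichever cytoskeletal mRNA is already high in the control IP. Across 22 myosin genes, which are not independent replicates, the change with genotype and the control IP level over input (log2) had a Spearman correlation of -0.0796 (permutation p = 0.725) and a Pearson correlation of -0.25 (p = 0.258). The control IP level enters both values with opposite sign, which pulls the correlation down and which the permutation does not remove. This test therefore left the hypothesis undecided.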
